A study of Saccharomyces cerevisiae with 20 samples.

How the data were processed

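Expression was measured on 20 one-colour Agilent yeast arrays in 5 groups of 4, which were a first control set, 5 mg of the yttrium salt and 3 mg of oxide on slides 1 and 2, and a second control set and 20 mg of oxide on slide 3. Replicates 1 and 2 of the first experiment lay on slide 1 and replicates 3 and 4 on slide 2, treated arrays lay in row 1 of a slide and control arrays in row 2. The volume that received each amount is not given in the sources used here. Each treatment was matched to its controls by shared slides.

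The spot intensities were produced with Feature Extraction 10.7.3.1 and protocol GE1_107_Sep09 per the file headers, which also give the genome build of the probe coordinates as sacCer2. The processed signal is an intensity that was background-subtracted and detrended within each array per the file headers, with no scaling between arrays. Flags for outlier, saturated and well above background spots, of 0 or 1, were set by the same software per the file headers. A deposited table of intensities for all samples held linear values with the same mean of 5698.66 on each array. Its identifiers did not match the probes, with a highest absolute correlation by identifier of 0.0058, so its entries were matched to probes by their profile across arrays. In this way 6149 of 6256 entries were matched, or 98.3 percent, and 107 were left out. The table was used only as an alternative.

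Each array had 13048 spots, 12512 of them not controls, for 6256 probes with 2 spots each. Spots with an outlier flag, 40 over all arrays, were left out, and no spot was saturated. The processed signal was put on a log2 scale, the 75th percentile of non-control spots was subtracted on each array, and the spots of a probe were averaged. For the 29 of 6225 systematic names with several probes, the probe with the highest mean log2 signal was used. Symbols came from the locus tag for 5748 probes, from a transcript accession for 17 and from the array file for 491, and 309 symbols differed from those in the file. A change of 1 log2 unit is 2-fold. Values given after a change are its standard error and the adjusted p.

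Differences were tested in R 4.3.3 with limma 3.58.1, with files read by the data.table package, version 1.17.8. A linear model with 5 groups was fitted to all 20 arrays, so that every comparison shared the same estimate of spread, with moderated t tests, two-sided. The Benjamini-Hochberg adjustment ran over the genes tested, and a gene was called at an adjusted p below 0.05. A gene was tested where its probe was well above background on all 4 arrays of at least 1 group of the comparison. Where the dimmer group was well above background on none of its arrays, the change is given as at least a stated fold. Each of 36 gene lists was fixed before the data were examined, and 33 had the 5 tested members needed in every main comparison. Lists were tested with camera in limma at a preset correlation between genes of 0.01. The Benjamini-Hochberg adjustment ran over the lists, and counts of members are also given with p adjusted over the list alone. An estimated correlation and the fry test were the alternatives.

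Genes were named by a rule fixed before the data were examined. It took the 8 largest rises and falls of each treatment against its controls, 5 each way for the other comparisons, up to 3 genes of each called list and 12 genes fixed beforehand. A rise or fall of the first kind needed an adjusted p below 0.05, no overlap between the 4 and 4 arrays, and a higher group well above background on all of its arrays. The text gives a part of the genes that the rule names, and says where a gene was chosen after its value was seen.

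The alternatives were quantile scaling, scaling by the array median, the deposited table, the normexp background model with offset 50 on the mean or on the median signal, a minimum of 2-fold, no filter on dim probes, only probes well above background on all arrays, the mean of all probes of a gene, variances with a trend and robust estimation, slide as a block or a random effect, each slide alone, replicate number as a block, fitting only the groups of a comparison, and leaving out each array in turn. The mean signal was used for the first experiment only, so the model on the median signal was added after the files were seen. Array signal as a covariate, leaving out 3 arrays in doubt, those of slide 3 with the lowest percent of probes well above background (85.9, 78.2 and 76), and averaging the oxide arrays in pairs were also added after the data were seen. Whether replicate numbers pair cultures across groups was checked on the residuals. Own numbers were the best match for 0 of 4 arrays between the first control set and the salt and 2 of 4 between that set and 3 mg of oxide, so no pairing was used. Changes were also added to 200 genes on simulated arrays, all drawn around the mean of control set 1 with 1 pooled spread per gene. In the salt, 3 mg and 20 mg comparisons 2-fold changes were recovered for 83.6, 77.6 and 95.5 percent of 67 genes each. False calls numbered 5, 5 and 11, and 1.5-fold changes were recovered for 53.7, 52.2 and 58.2 percent. The simulated arrays held none of the dimness or pairing of the real ones, so these values do not rank the treatments by sensitivity.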

Results

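Expression was measured in the laboratory yeast strain S288C, the strain behind the reference genome of *Saccharomyces cerevisiae*, after exposure to yttrium in a soluble and a particulate form. Cultures grew for 6 h at 30 °C in YPD, a rich medium of yeast extract, peptone and glucose, and were then exposed for 2 h. The soluble form was 5 mg of yttrium chloride hexahydrate, and the particulate form was Y2O3 nanoparticle, an oxide that dissolves poorly in water, at 3 mg or 20 mg. Total RNA was labelled with Cy3 and hybridised to 20 one-colour Agilent arrays, 4 for each of 5 groups. The labels state that the 4 samples of each group were independent biological samples. The salt, the 3 mg oxide and the first control set shared slides 1 and 2, and the 20 mg oxide and the second control set shared slide 3. Every treated culture was therefore compared with the controls on its own slides.

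Each treatment was compared with its controls to ask which genes respond to dissolved yttrium, to a small amount of the oxide and to a larger amount. The salt was also compared directly with the 3 mg oxide, to ask whether the 2 treatments act alike. These differed in amount as well as in form, so form and amount cannot be told apart there. The responses to 20 mg were compared with those to 3 mg and to the salt, each against its own controls, to ask how far the responses differ. Against the salt, form and amount again differed together. The 2 control sets were compared to measure how far untreated cultures differed between the experiments. The number of arrays, 4 per group, limits the precision of every value. The median standard error of a log2 change was 0.177 for the salt and for the 3 mg oxide and 0.173 for the 20 mg oxide. The fit pooled the spread of all groups, so these values are nearly equal by construction. Within groups the median SD was 0.193 in control set 1, 0.289 with the salt and 0.1 with 3 mg. It was 0.173 in control set 2 and 0.195 with 20 mg.

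The 75th percentile of signal ranged from 404.3 to 11713.1 across arrays. In the 20 mg group it was 404.3, 435, 407.6 and 1004.2, in control set 2 it was 412 for replicate 1 and 2180.1 to 3416.2 for the others, and no array of the first experiment was below 3970.1. Between 76 and 94 percent of probes were well above background on each array. Across 4657 genes the correlation between arrays of a group was 0.947 to 0.995 in control set 1, 0.923 to 0.977 with the salt, 0.991 to 0.998 with 3 mg of oxide, 0.972 to 0.995 in control set 2 and 0.953 to 0.990 with 20 mg. The oxide arrays fell into pairs, with replicates 1 and 2 and replicates 3 and 4 closest to each other. At 3 mg both pairs correlated at 0.998, against at most 0.994 across pairs, and at 20 mg at 0.990 and 0.988, against at most 0.975. At 3 mg the pairs were also the arrays of slides 1 and 2, so pair and slide cannot be told apart. At 20 mg the percent of probes well above background was 87.3 and 89.3 in replicates 1 and 2 and 78.2 and 76 in replicates 3 and 4. The arrays do not show whether the members of a pair came from separate cultures. If they did not, each oxide group holds 2 cultures and the standard errors given with n = 4 are too small.

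Phosphate genes fell in both treatments of the first experiment, and with 3 mg of oxide they were nearly the whole response. The high-affinity phosphate transporter PHO84 (YML123C, probe at chromosome XIII 24138 to 24197, build sacCer2) fell by 3.65 log2 units with 3 mg of oxide (standard error 0.46, n = 4, adjusted p = 0.000157). SPL2 (YHR136C, chromosome VIII 374787 to 374846), which restrains low-affinity phosphate transport, fell by 4.82 (standard error 0.31, adjusted p = 1.47e-08). The secreted acid phosphatase PHO5 (YBR093C, chromosome II 430022 to 430081) fell by 3.61 (0.40, adjusted p = 4.16e-05), and the sodium and phosphate cotransporter PHO89 (YBR296C, chromosome II 796894 to 796953) fell by 4.93 (0.72, adjusted p = 0.00112). VTC3, part of the vacuolar complex that makes polyphosphate, fell by 2.52 (0.26, adjusted p = 1.64e-05). The fixed list of phosphate starvation genes had a median change of -1.73, with 14 of 19 members down, 0 up and 5 not called (camera adjusted p = 1.47e-85, and 2.19e-05 with an estimated correlation). Adjusted over the list alone, 17 members fell.

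Other phosphate genes that fell with 3 mg of oxide were PHM6, which is induced when phosphate runs short (-2.71, standard error 0.48, adjusted p = 0.00785), the acid phosphatase PHO11 (-1.97, 0.36, adjusted p = 0.0114) and the glycerophosphoinositol transporter GIT1 (-1.82, 0.28, adjusted p = 0.00135). Only 2 genes rose, the phospholipase PLB3 by 0.76 (0.11, adjusted p = 0.00126) and the low-affinity phosphate transporter PHO87 by 0.72 (0.13, adjusted p = 0.00801). In all, limma called 16 of 5664 genes, all 14 of the falls belonging to the phosphate list, and 12 of the 16 changed at least 2-fold. At unadjusted p below 0.05 there were 164 genes, fewer than the share of 0.05 of all genes tested that chance alone would give. The 4 treated and 4 control arrays did not overlap for 371 genes, or 6.6 percent, against 2.86 percent by chance. With the oxide arrays averaged in their pairs 11 genes were called, all falls. Among the genes named here PLB3, PHO87 and PHO89 then lost their calls (adjusted p = 0.0711, 0.391 and 0.0511).

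Of the 12 genes fixed beforehand, only PHO84, SPL2, PHO5 and VTC3 changed with 3 mg of oxide. The small heat shock protein gene HSP26 (-0.37, standard error 0.42), the membrane chaperone HSP12 (-0.16, 0.47), the sodium pump ENA1 (-0.49, 0.19), the vacuolar calcium pump PMC1 (-0.32, 0.20), the zinc transporter ZRT1 (-0.05, 0.21), the metallothionein CUP1-1 (0.12, 0.38) and the iron oxidase FET3 (0.09, 0.34) each had an adjusted p of 1. The cell wall mannoprotein FIT2, which retains iron, was not called either (-0.92, 0.30, adjusted p = 0.807). GIT1 lost its call with quantile scaling (adjusted p = 0.448) and with the deposited value table (0.398). It also lost it with background modelled on the median signal, where its adjusted p was 1 and that of PHO87 was 0.0996. PHO11 lost its call without replicate 1 at 3 mg (adjusted p = 0.0536), and PHO89 when only the arrays of the comparison were fitted (0.0515). Without replicate 4 of control set 1, the highest of its group, PHO89 fell by 3.93.

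A further 9 lists were called with 3 mg of oxide although none of their members was called at the gene level. Ribosome biogenesis, the genes that assemble ribosomes, rose by a median of 0.23 (adjusted p = 8.31e-10), and ribosomal proteins by 0.08 (adjusted p = 0.0262). Amino acid synthesis genes under Gcn4 rose by 0.10 (adjusted p = 0.0287). Trehalose and glycogen genes, which handle storage sugars, fell by 0.25 (adjusted p = 4.96e-05), general stress genes under Msn2 and Msn4 by 0.23 (0.00356), cell wall genes by 0.19 (0.00051) and proteasome genes by 0.10 (0.00051). Calcineurin targets under Crz1 fell by 0.19 (adjusted p = 0.0166), and glycolysis genes by 0.09 (0.0193). Adjusted over the list alone, 3 cell wall genes and 1 general stress gene fell. None of the 9 was called with an estimated correlation, with an adjusted p of 0.884 for ribosomal proteins and 0.838 for the other 8. Without replicate 4 of control set 1 only 1 list was called, the general stress median turned to 0.13 and the trehalose and glycogen median was -0.02.

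The slides carried the first experiment as 2 batches, and the median of the phosphate list was nearly the same on both, while single genes varied more. With slide as a block 17 genes were called with 3 mg of oxide, and within slides 1 and 2 alone 9 and 3. The phosphate list had a median of -1.73 with slide as a block, and of -1.80 and -1.68 within slides 1 and 2. Within the 2 slides SPL2 changed by -5.25 and -4.40, PHO5 by -3.86 and -3.35, PHO84 by -4.59 and -2.71 and PHO89 by -4.22 and -5.64. The small list shifts were less stable. General stress genes changed by -0.06 on slide 1 (adjusted p = 0.83) and -0.41 on slide 2, and ribosomal proteins by -0.03 and 0.21. On slide 1 the Crz1 median was 0.04 (adjusted p = 0.777).

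**Figure D1:**
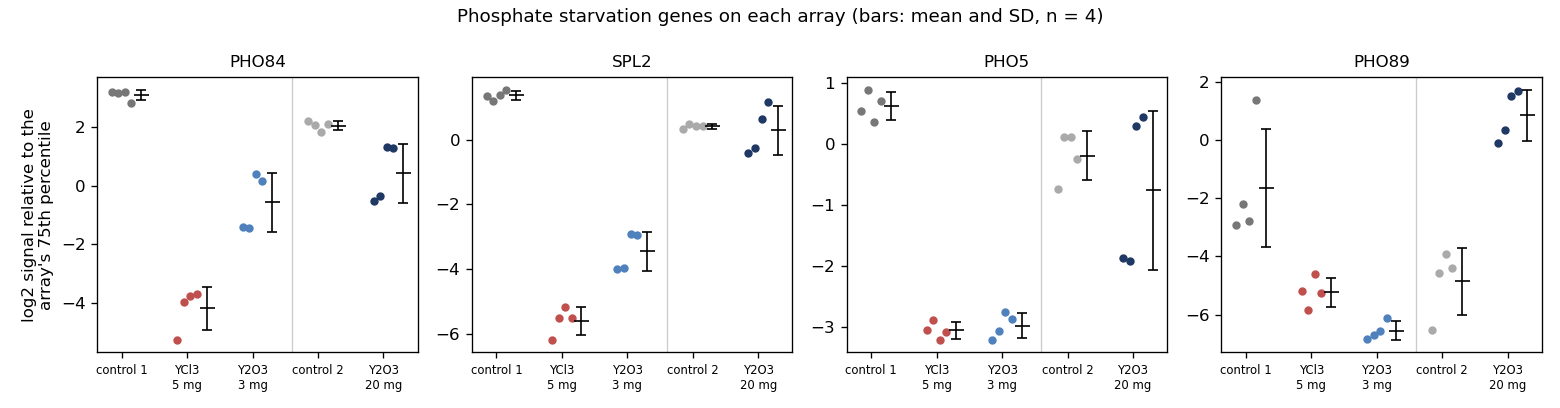
Log2 signal relative to the 75th percentile of the array for PHO84, SPL2, PHO5 and PHO89 in the 5 groups, with points for arrays and bars for mean and SD (n = 4). Mean PHO84 signal was 3.08 in control set 1, -4.17 with the salt and -0.58 with 3 mg of oxide, and mean PHO89 signal was 0.87 with 20 mg against -4.85 in control set 2.

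With the yttrium salt phosphate genes also fell, while methionine and sulfate genes and genes of nitrogen catabolite repression rose. PHO84 fell by 7.24 log2 units (standard error 0.46, n = 4, adjusted p = 4.17e-10), SPL2 by 6.97 (0.31, adjusted p = 1.87e-12), PHO5 by 3.69 (0.40, adjusted p = 9.46e-07) and VTC3 by 2.96 (0.26, adjusted p = 4.64e-08). The sulfate transporter SUL1 (YBR294W, chromosome II 791566 to 791625) rose by 8.64 (0.47, adjusted p = 2.9e-11), which is at least 120-fold because no control array was well above background. ARO10 (YDR380W, chromosome IV 1235861 to 1235920), a decarboxylase of aromatic amino acid breakdown, fell by 8.49 (0.22, adjusted p = 3.96e-16). The ammonium transporter MEP2 (YNL142W, chromosome XIV 358662 to 358721) rose by 5.98 (0.15, adjusted p = 3.96e-16). Limma called 2077 of 5696 genes, 995 up and 1082 down, or 36.5 percent. At least 2-fold changes numbered 561, 376 up and 185 down, and the arrays did not overlap for 1571 genes, or 27.6 percent, against 2.86 percent by chance.

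Other large rises with the salt were in INO1 (YJL153C), which makes inositol phosphate (6.90, standard error 0.66, adjusted p = 1.45e-07), and the nitrogen regulator DAL80 (YKR034W), up 6.73 (0.35, adjusted p = 2.1e-11) or at least 46.0-fold. The zinc transporter ZRT1 rose by 5.29 (0.21, adjusted p = 4.65e-13) and ZPS1, a cell surface protein made when zinc is scarce, by 5.17 (0.50, adjusted p = 1.66e-07). The general amino acid permease GAP1 rose by 4.95 (0.32, adjusted p = 5.63e-10) and the proline permease PUT4 by 4.74 (0.39, adjusted p = 1.98e-08). The largest other falls were in the branched-chain amino acid permease BAP3 (-6.76, 0.25, adjusted p = 1.26e-13), the peptide transporter PTR2 (-6.45, 0.27, adjusted p = 7.68e-13) and the oligopeptide transporter OPT2 (-5.88, 0.25, adjusted p = 1.16e-12, at least 23.6-fold). The aromatic aminotransferase ARO9 fell by 5.68 (0.25, adjusted p = 1.83e-12) and FRE7, a metal reductase made when copper is scarce, by 5.64 (0.30, adjusted p = 2.26e-11).

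The phosphate list had a median of -2.00 with the salt, with 15 of 19 members down, 0 up and 4 not called (camera adjusted p = 6.23e-11, and 0.114 with an estimated correlation). Genes of methionine synthesis and sulfate uptake rose by a median of 2.55, with 22 of 27 up, 3 down and 2 not called (adjusted p = 1.14e-18, and 0.0532 with an estimated correlation). The transferase MET2 rose by 4.67 (standard error 0.37, adjusted p = 1.01e-08) and the ATP sulfurylase MET3 by 4.59 (0.24, adjusted p = 2.26e-11). Genes held down by good nitrogen sources, the nitrogen catabolite repression list, rose by a median of 1.72 with 20 of 24 up, 1 down and 3 not called (adjusted p = 1.21e-16). This list alone kept its call with an estimated correlation (adjusted p = 0.00169). Amino acid synthesis genes rose by 0.75, with 30 of 48 up and 2 down (adjusted p = 7.52e-11, and 0.159 with an estimated correlation). Examples were the arginine genes ARG3 (3.33, 0.29, adjusted p = 3.42e-08) and CPA1 (2.68, 0.19, adjusted p = 2.02e-09) and the leucine gene LEU1 (2.46, 0.24, adjusted p = 1.55e-07). Counts over each list alone were 15 down for phosphate, 23 up and 3 down for methionine, 21 up and 1 down for nitrogen and 31 up and 2 down for amino acid synthesis.

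Among metal and lipid genes, the zinc list under Zap1 rose by a median of 1.76 with the salt, with 11 of 13 up and 2 down, the same over the list alone (adjusted p = 1.82e-06, and 0.159 with an estimated correlation). The iron uptake list rose by 0.53, with 11 of 23 up and 3 down by both adjustments (adjusted p = 0.00303, and 0.305 with an estimated correlation). Within it the siderophore transporter ARN1 rose by 2.12 (standard error 0.33, adjusted p = 7.65e-05) and the mannoprotein FIT1 by 1.61 (0.15, adjusted p = 1.15e-07), while the reductase FRE1 fell by 2.67 (0.30, adjusted p = 1.5e-06). FET3 (0.45, 0.34, adjusted p = 0.314) and FIT2 (0.32, 0.30, adjusted p = 0.42) were not called. Phospholipid and inositol genes rose by 0.72, with 16 of 21 up and 0 down by both adjustments (adjusted p = 1.54e-08, and 0.0645 with an estimated correlation). The methyltransferase OPI3 rose by 2.70 (0.32, adjusted p = 2.64e-06), and so did OPI1, the repressor of these genes (1.59, 0.30, adjusted p = 0.000419).

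Further lists rose with the salt on smaller shifts. Gluconeogenesis genes rose by 0.65, with 11 of 23 up and 0 down (adjusted p = 1.6e-05, and 0.119 with an estimated correlation), among them the lactate transporter JEN1 (1.96, standard error 0.37, adjusted p = 0.000516) and isocitrate lyase ICL1 (1.90, 0.13, adjusted p = 1.52e-09). DNA damage genes rose by 0.87, with 12 of 18 up and 1 down (14 and 1 over the list alone, adjusted p = 0.000236, and 0.305 with an estimated correlation). The ribonucleotide reductase RNR3 rose by 3.37 (0.59, adjusted p = 0.000224) and the photolyase PHR1 fell by 1.49 (0.17, adjusted p = 2.19e-06). Salt replicate 4 stayed near the controls for RNR3, at -3.129, and without it RNR3 rose by 4.36. Thiamine genes rose by 0.59, with 11 of 18 up and 1 down (13 and 1 over the list alone, adjusted p = 0.000172, and 0.271 with an estimated correlation). The thiazole synthase THI4 rose by 2.06 (0.15, adjusted p = 4.07e-09), and the thiamine-repressed phosphatase PHO3 fell by 2.85 (0.23, adjusted p = 1.57e-08). Ribosome biogenesis rose by 0.33, with 17 of 65 up and 0 down (12 over the list alone, adjusted p = 0.00148, and 0.676 with an estimated correlation), including the processome genes UTP5 (1.29, 0.28, adjusted p = 0.00164) and NOC4 (1.15, 0.23, adjusted p = 0.000795). This list call rested on replicate 4 of control set 1, without which the median was 0.09 (adjusted p = 0.223). The list of a-specific mating genes rose by 0.91 with 3 of 5 up (adjusted p = 0.00994, and 0.178 with an estimated correlation), among them ASG7, a regulator of mating signals, well above background on 1 control array (1.86, 0.23, adjusted p = 6.11e-06). With background modelled on the mean or the median signal the median of this list was 0.21 or 0.19 and the call was lost (adjusted p = 0.223 and 0.493).

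Chaperone and ribosomal protein genes fell with the salt. Heat shock chaperones fell by a median of 0.86, with 19 of 23 down and 0 up (19 down and 1 up over the list alone, adjusted p = 1.22e-08, and 0.132 with an estimated correlation). The sorting factor BTN2 fell by 2.78 (standard error 0.38, adjusted p = 1.55e-05), the cochaperone SIS1 by 1.62 (0.17, adjusted p = 4.12e-07) and the chaperone HSP82 by 1.52 (0.17, adjusted p = 1.03e-06). Ribosomal proteins fell by 0.58, with 52 of 136 down and 1 up (65 and 1 over the list alone, adjusted p = 2.7e-09, and 0.582 with an estimated correlation), among them RPL41A (-1.03, 0.23, adjusted p = 0.00235) and RPL17B (-0.92, 0.20, adjusted p = 0.00147). Histones fell by 0.82, with 8 of 11 down and 0 up (9 and 1 over the list alone, adjusted p = 0.0174, and 0.547 with an estimated correlation), as in HTB2, a gene for histone H2B (-1.61, 0.42, adjusted p = 0.00679). Salt replicate 4 did not share the fall of HTB2, at 1.642 against a control mean of 1.74, and without it the change was -2.11.

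Trehalose and glycogen genes fell by 0.47 with the salt, with 8 of 17 down by both adjustments (adjusted p = 0.0203, and 0.623 with an estimated correlation), led by the trehalose synthase subunit TSL1 (-1.62, standard error 0.24, adjusted p = 4.73e-05). This list was not called without replicate 4 of control set 1 (median -0.3, adjusted p = 0.214). Vacuolar proton pump genes fell by 0.33, with 3 of 14 down and none over the list alone (adjusted p = 0.0203, and 0.305 with an estimated correlation), among them VMA8 (-0.44, 0.15, adjusted p = 0.0319). Unfolded protein genes fell by 0.17, with 6 of 20 down by both adjustments (adjusted p = 0.0486, and 0.178 with an estimated correlation), among them the endoplasmic reticulum chaperone KAR2 (-0.90, 0.13, adjusted p = 2.74e-05). General stress genes were not called as a list (median 0.36, 7 of 24 up and 4 down, adjusted p = 0.218), but were called without replicate 4 of control set 1 (0.71, adjusted p = 0.0021), and HSP12 rose by 1.46 (0.47, adjusted p = 0.0211). HSP26 (0.39, 0.42, adjusted p = 0.485), CUP1-1 (0.39, 0.38, adjusted p = 0.44), PMC1 (-0.05, 0.20, adjusted p = 0.858) and ENA1 (-0.04, 0.19, adjusted p = 0.902) were not called. The copper list had a median of 0.12 but a mean of -0.77 (adjusted p = 0.206). Oxidative stress, with 9 of 26 members up and 6 down, was not called either (median 0.24, adjusted p = 0.126). Without replicate 4 of control set 1 it was called (median 0.4, adjusted p = 0.0387).

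Of 34 lists tested with the salt, 18 were called, 11 up and 7 down, and 1 with an estimated correlation. Several smaller calls rested on particular settings. HSP12 lost its call when only the arrays of the comparison were fitted (adjusted p = 0.094) and without replicate 1 or 3 of control set 1 (0.0838 and 0.0768), and HTB2 when only those arrays were fitted (0.0671). VMA8 lost it with quantile scaling (0.06), and ASG7 with background modelled on the median signal (0.455). CUP1-1 was called without salt replicate 3, with a rise of 0.86 (adjusted p = 0.0392). Without replicate 4 of control set 1 the rise was 7.94 for INO1 and 2.10 for HSP12, and ZPS1 rose by 5.78 without salt replicate 2 and by 4.58 without salt replicate 4. Unfolded protein, vacuolar pump and a-specific genes lost their list calls with quantile scaling (adjusted p = 0.0759, 0.151 and 0.106). Trehalose genes and histones lost theirs with background modelled on the mean signal (0.0567 each). Without replicate 4 of control set 1 trehalose (0.214) and ribosome biogenesis genes (0.223) were not called. General stress (0.0021), oxidative stress (0.0387), cell wall (0.0344) and stationary phase genes (0.0318) were then called as rising. No called list changed direction relative to the other genes under any scaling.

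With slide as a block 2096 genes and 18 lists were called with the salt, and within slides 1 and 2 alone 1026 and 308 genes and 21 and 15 lists. The phosphate list had a median of -2.00 with slide as a block, and of -2.01 and -2.02 within the slides. Methionine genes changed by 2.6 and 2.62 within the 2 slides, nitrogen genes by 1.63 and 1.86, heat shock chaperones by -0.80 and -0.88 and ribosomal proteins by -0.59 and -0.54. SUL1 rose by 8.66 and 8.62 within slides 1 and 2, MEP2 by 5.65 and 6.31 and INO1 by 7.63 and 6.17, while ARO10 changed by -8.37 and -8.61 and PHO84 by -7.77 and -6.72. On slide 1 alone trehalose genes (adjusted p = 0.262) and ribosome biogenesis (0.108) were not called. On slide 2 alone unfolded protein genes (0.149), histones (0.245) and vacuolar pump genes (0.217) were not.

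**Figure D2:**
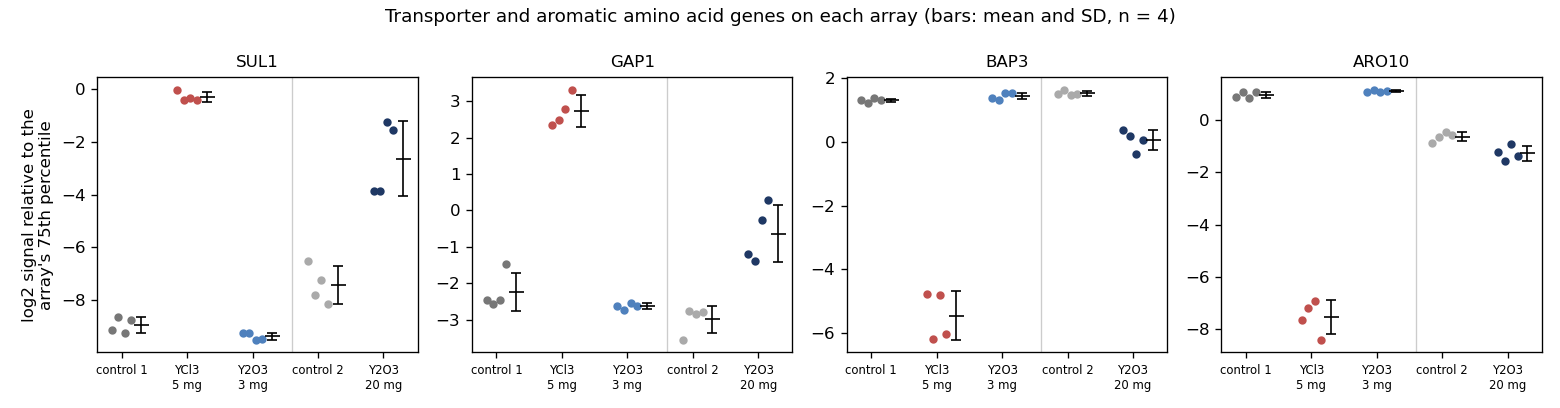
Log2 signal relative to the 75th percentile of the array for SUL1, GAP1, BAP3 and ARO10 in the 5 groups, with points for arrays and bars for mean and SD (n = 4). Mean SUL1 signal was -8.94 in control set 1 and -0.30 with the salt, and mean ARO10 signal was 0.95 and -7.54.

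With 20 mg of oxide most of the genome changed, and ribosome genes fell while stress and detoxification genes rose. RPL24A, a ribosomal protein gene, fell by 4.75 log2 units (standard error 0.22, n = 4, adjusted p = 1.19e-12). The RNA helicase DBP2 (YNL112W, chromosome XIV 416050 to 416109) fell by 6.03 (0.32, adjusted p = 7.48e-12), or at least 27.4-fold. OYE3 (YPL171C, chromosome XVI 226296 to 226355), an oxidoreductase induced by oxidants, rose by 9.04 (0.29, adjusted p = 1.76e-14). INO1 (chromosome X 134537 to 134596) rose by 10.30 (0.66, adjusted p = 8.17e-11). Limma called 3983 of 5401 genes, 1864 up and 2119 down, or 73.7 percent, with 2204 changed at least 2-fold. The arrays did not overlap for 3677 genes, or 68.1 percent, against 2.86 percent by chance. With the oxide arrays averaged in their pairs 3513 genes were called.

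Other large rises with 20 mg were in RGI2, a gene of respiratory growth (8.52, standard error 0.43, adjusted p = 4.25e-12), OSI1, induced by oxidants (8.12, 0.25, adjusted p = 1.76e-14), the mitochondrial protein gene SHH3 (7.49, 0.32, adjusted p = 6.65e-13) and the uncharacterised YBR116C (7.34, 0.50, adjusted p = 1.67e-10). The cell wall protein PIR3 rose by 7.22 (0.34, adjusted p = 1.76e-12) and the hexose transporter HXT5 by 7.0 (0.71, adjusted p = 3.69e-08). Other large falls were in the phosphatase PHO3 (-5.99, 0.23, adjusted p = 2.51e-13, at least 29.9-fold) and the pheromone gene MF(ALPHA)2 (-5.48, 0.29, adjusted p = 8.44e-12). Nucleotide genes also fell, namely the IMP dehydrogenase IMD2 (-5.02, 0.30, adjusted p = 2.44e-11, at least 14.2-fold), the adenine deaminase AAH1 (-5.02, 0.30, adjusted p = 2.59e-11) and the CTP synthase URA7 (-4.94, 0.34, adjusted p = 2.05e-10). HO, the mating type endonuclease, fell by 4.87 (0.48, adjusted p = 2.97e-08, at least 18.2-fold). RGI2 was well above background on 1 control array, and AAH1 and MF(ALPHA)2 on 1 and 2 arrays at 20 mg, so the sizes of these changes, and their order beside the bounds, are uncertain.

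Ribosomal proteins fell by a median of 3.09 with 20 mg, with 135 of 136 down and 0 up (camera adjusted p = 1.86e-29, and 0.212 with an estimated correlation). RPL21A fell by 4.61 (standard error 0.23, adjusted p = 2.73e-12, at least 14.9-fold) and RPL8A by 4.50 (0.24, adjusted p = 6.96e-12). Ribosome biogenesis fell by 2.62 with all 65 members down (adjusted p = 1.34e-17, and 0.212 with an estimated correlation), among them the RNA polymerase I subunits RPA43 (-4.42, 0.24, adjusted p = 8.44e-12) and RPA135 (-4.28, 0.26, adjusted p = 3.1e-11) and the nucleolar methyltransferase NOP1 (-4.15, 0.45, adjusted p = 8.88e-08). Amino acid synthesis genes fell by 1.67, with 38 of 48 down and 3 up (adjusted p = 7.35e-08, and 0.212 with an estimated correlation), as in the leucine gene LEU9 (-4.33, 0.27, adjusted p = 7.35e-11), the arginine gene ARG1 (-4.17, 0.28, adjusted p = 1.69e-10) and the histidine gene HIS1 (-4.02, 0.28, adjusted p = 2.75e-10). RPA43 was well above background on 1 array at 20 mg, and RPA135 and LEU9 on 2, so the sizes of these falls are uncertain. Counts adjusted over each list alone were the same for every list called with 20 mg.

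General stress genes rose by a median of 3.37 with 20 mg, with all 23 tested members up (adjusted p = 1.76e-10, and 0.212 with an estimated correlation). The hydrophilin GRE1 rose by 6.81 (standard error 0.35, adjusted p = 6.39e-12), the phosphogluconate dehydrogenase GND2 by 6.57 (0.45, adjusted p = 2.16e-10), the stress gene DDR2 by 5.62 (0.31, adjusted p = 1.23e-11) and HSP12 by 4.89 (0.47, adjusted p = 1.8e-08). Oxidative stress genes under Yap1 rose by 1.93, with 22 of 26 up and 2 down (adjusted p = 3.84e-08, and 0.0708 with an estimated correlation), including the glutathione transferases GTT2 (6.28, 0.36, adjusted p = 2.12e-11) and ECM4 (5.44, 0.25, adjusted p = 1.32e-12). Drug resistance genes under Pdr1 and Pdr3 rose by 2.73, with 15 of 16 up and 1 down (adjusted p = 1.07e-07, and 0.114 with an estimated correlation). RTA1, of the lipid-translocating exporter family, well above background on 1 control array, rose by 6.01 (0.72, adjusted p = 3.4e-07), the drug pump PDR10 by 5.74 (0.25, adjusted p = 6.65e-13) and the reductase GRE2 by 5.45 (0.25, adjusted p = 1.16e-12).

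All 36 proteasome genes rose with 20 mg, by a median of 1.01 (adjusted p = 1.1e-09, and 0.187 with an estimated correlation), together with their activator RPN4 (3.17, standard error 0.14, adjusted p = 7.02e-13) and the subunits RPN12 (1.52, 0.13, adjusted p = 4.17e-09) and PRE3 (1.48, 0.13, adjusted p = 4.1e-09). Heat shock chaperones rose by 1.35, with 19 of 23 up and 1 down (adjusted p = 3.26e-05, and 0.212 with an estimated correlation), as in SSA3 (3.42, 0.18, adjusted p = 7.77e-12), HSP26 (2.87, 0.42, adjusted p = 4.19e-06) and HSP42 (2.36, 0.21, adjusted p = 7.28e-09). Methionine and sulfate genes rose by 2.95, with 25 of 27 up and 2 down (adjusted p = 1.1e-09, and 0.153 with an estimated correlation). MET2 rose by 5.03 (0.37, adjusted p = 4.32e-10), SUL1 by 4.79 (0.47, adjusted p = 2.19e-08, at least 15.6-fold) and the activator MET28 by 4.65 (0.16, adjusted p = 6.1e-14).

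Carbon and respiration genes rose with 20 mg. Gluconeogenesis genes rose by a median of 2.08, with 20 of 22 up and 1 down (adjusted p = 1.7e-07, and 0.0708 with an estimated correlation), led by the acetate transporter ADY2 (4.55, standard error 0.18, adjusted p = 3.4e-13), JEN1 (3.94, 0.37, adjusted p = 1.37e-08) and the activator CAT8 (3.65, 0.39, adjusted p = 8.77e-08). Oxidative phosphorylation rose by 0.94, with 34 of 38 up and 1 down (adjusted p = 7.9e-07, and 0.293 with an estimated correlation), including the NADH dehydrogenase NDE2 (5.52, 0.47, adjusted p = 3.22e-09) and STF1, a regulator of the ATP synthase (2.53, 0.28, adjusted p = 1.54e-07). The tricarboxylic acid cycle rose by 0.73, with 14 of 16 up and 1 down (adjusted p = 0.00151, and 0.328 with an estimated correlation), as in the citrate synthase CIT3 (2.51, 0.21, adjusted p = 1.99e-09). Trehalose and glycogen genes rose by 1.45, with 13 of 17 up and 0 down (adjusted p = 0.000335, and 0.328 with an estimated correlation), among them the phosphatase subunit GAC1 (3.1, 0.25, adjusted p = 1.61e-09) and TSL1 (2.12, 0.24, adjusted p = 1.88e-07). Stationary phase genes rose by 2.20, with 11 of 15 up and 0 down (adjusted p = 0.000103, and 0.153 with an estimated correlation), including the mitochondrial gene FMP16 (6.52, 0.45, adjusted p = 1.95e-10) and SPG4, needed for survival in stationary phase (5.73, 0.68, adjusted p = 2.95e-07).

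Nitrogen catabolite genes rose by 0.94 with 20 mg, with 15 of 22 up and 5 down (adjusted p = 0.00868, and 0.212 with an estimated correlation), among them PUT4 (2.76, standard error 0.39, adjusted p = 3.17e-06) and the proline oxidase PUT1 (2.39, 0.30, adjusted p = 6.65e-07). Phospholipid and inositol genes rose by 0.59, with 15 of 21 up and 4 down (adjusted p = 0.00405, and 0.235 with an estimated correlation), as in OPI3 (3.59, 0.32, adjusted p = 6.29e-09) and the inositol transporter ITR1 (2.36, 0.25, adjusted p = 8.48e-08). Calcineurin targets rose by 0.83, with 11 of 17 up and 2 down (adjusted p = 0.0403, and 0.357 with an estimated correlation). The sodium pumps ENA2 (2.04, 0.18, adjusted p = 7.36e-09) and ENA1 (1.67, 0.19, adjusted p = 2.06e-07) and the calcium pump PMC1 (1.90, 0.20, adjusted p = 8.77e-08) rose.

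Cell cycle genes fell with 20 mg. The G1/S list fell by a median of 1.47, with 21 of 23 down and 0 up (adjusted p = 3.9e-05, and 0.13 with an estimated correlation), including the ribonucleotide reductase RNR1 (-4.27, standard error 0.24, adjusted p = 1.29e-11), the cohesin subunit MCD1 (-3.56, 0.19, adjusted p = 1.08e-11) and the cyclin CLB6 (-2.62, 0.26, adjusted p = 2.65e-08, at least 2.24-fold). The G2/M list fell by 1.22, with 12 of 15 down and 0 up (adjusted p = 0.00718, and 0.359 with an estimated correlation), as in the cyclins CLB2 (-4.04, 0.28, adjusted p = 2.38e-10, at least 6.10-fold) and CLB1 (-3.53, 0.28, adjusted p = 1.41e-09). Ergosterol genes fell by 0.67, with 19 of 28 down and 1 up (adjusted p = 0.00718, and 0.357 with an estimated correlation), among them the sterol reductase ERG4 (-2.61, 0.32, adjusted p = 5.82e-07) and the desaturase ERG3 (-2.51, 0.29, adjusted p = 2.12e-07). Vacuolar proton pump genes fell by 0.64, with 9 of 14 down and 0 up (adjusted p = 0.0318, and 0.293 with an estimated correlation), including VPH1 (-1.38, 0.16, adjusted p = 1.75e-07) and VMA5 (-1.24, 0.11, adjusted p = 1.05e-08).

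The phosphate list was not called with 20 mg, and its median of -0.57 and mean of 0.15 differed in sign (17 tested, 3 up and 7 down, adjusted p = 0.551). PHO84 fell by 1.61 (standard error 0.46, adjusted p = 0.00371) and VTC3 by 1.41 (0.26, adjusted p = 7.59e-05), while PHO5 (-0.57, 0.40, adjusted p = 0.209) and SPL2 (-0.13, 0.31, adjusted p = 0.719) were not called. The 3 members that rose, chosen for naming after their values were seen, were PHO89 (5.72, 0.72, adjusted p = 7.17e-07), the membrane protein gene PHM7 (4.37, 0.42, adjusted p = 1.57e-08) and the phosphatase PHM8 (2.92, 0.28, adjusted p = 2.1e-08). With array signal as a covariate PHO84 was no longer called (-1.37, adjusted p = 0.0559). PHO5 was called without replicate 3 or 4 at 20 mg alone, with changes of -0.924 and -0.973 (adjusted p = 0.0411 and 0.0242). Without the 3 arrays in doubt, replicate 1 of control set 2 and replicates 3 and 4 at 20 mg, PHO5 fell by 1.89 (adjusted p = 9.66e-08) and SPL2 by 0.78 (adjusted p = 0.0347). That fit set dim 20 mg arrays against brighter controls only, so signal and treatment cannot be told apart in it. FET3 fell by 3.13 (0.34, adjusted p = 9.51e-08), whereas ZRT1 (-0.23, 0.21, adjusted p = 0.327), CUP1-1 (-0.25, 0.38, adjusted p = 0.557) and FIT2 (0.51, 0.30, adjusted p = 0.135) were not called. FIT2 was called as rising with quantile scaling (0.733, adjusted p = 0.0381) and with the deposited table (0.748, 0.0418). It was also called when only the arrays of the comparison were fitted (0.0365), and with background modelled on the median signal (1.559, 0.00335). The zinc list (median -0.20, 2 of 12 up and 4 down, adjusted p = 0.551) and the iron list (0.50, 12 of 22 up and 6 down, adjusted p = 0.15) were not called.

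Of 33 lists tested with 20 mg, 21 were called, 14 up and 7 down, and 0 with an estimated correlation, where camera gave a lowest adjusted p of 0.0708, while the fry test called 30. With background modelled on the median signal, the median change of all genes moved by 0.492, and with the array median as the scale by 0.126. Relative to all genes after that background model, ribosomal proteins changed by -3.29, ribosome biogenesis by -1.67, general stress genes by 2.59, methionine genes by 2.18 and proteasome genes by 0.33. No called list turned relative to the other genes, but calcineurin targets, the tricarboxylic acid cycle and G2/M lost their calls (adjusted p = 0.184, 0.22 and 0.183). The G2/M median was then -0.03. CLB6 then changed by 0.59 (adjusted p = 0.215) and ZRT1 by 1.05 (adjusted p = 0.0131), both opposite in sign to the values above, and CLB2 was not called (-0.48, adjusted p = 0.302). The share of called genes that rose moved from 46.8 to 69.9 percent.

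**Figure D3:**
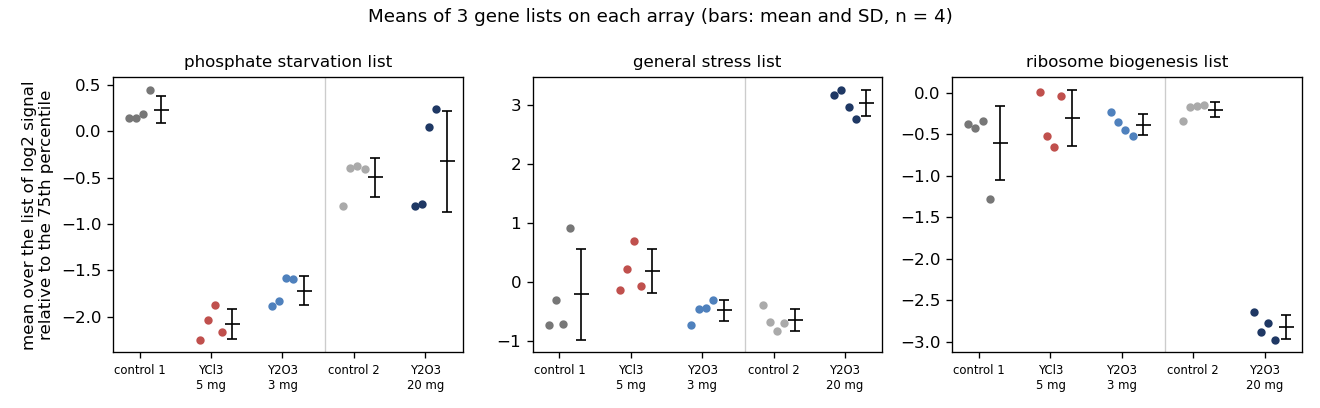
Mean log2 signal relative to the 75th percentile of the array over the phosphate, general stress and ribosome biogenesis lists, with points for arrays and bars for mean and SD (n = 4). General stress means were 2.77 to 3.26 with 20 mg of oxide and -0.82 to -0.39 in control set 2.

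**Figure D4:**
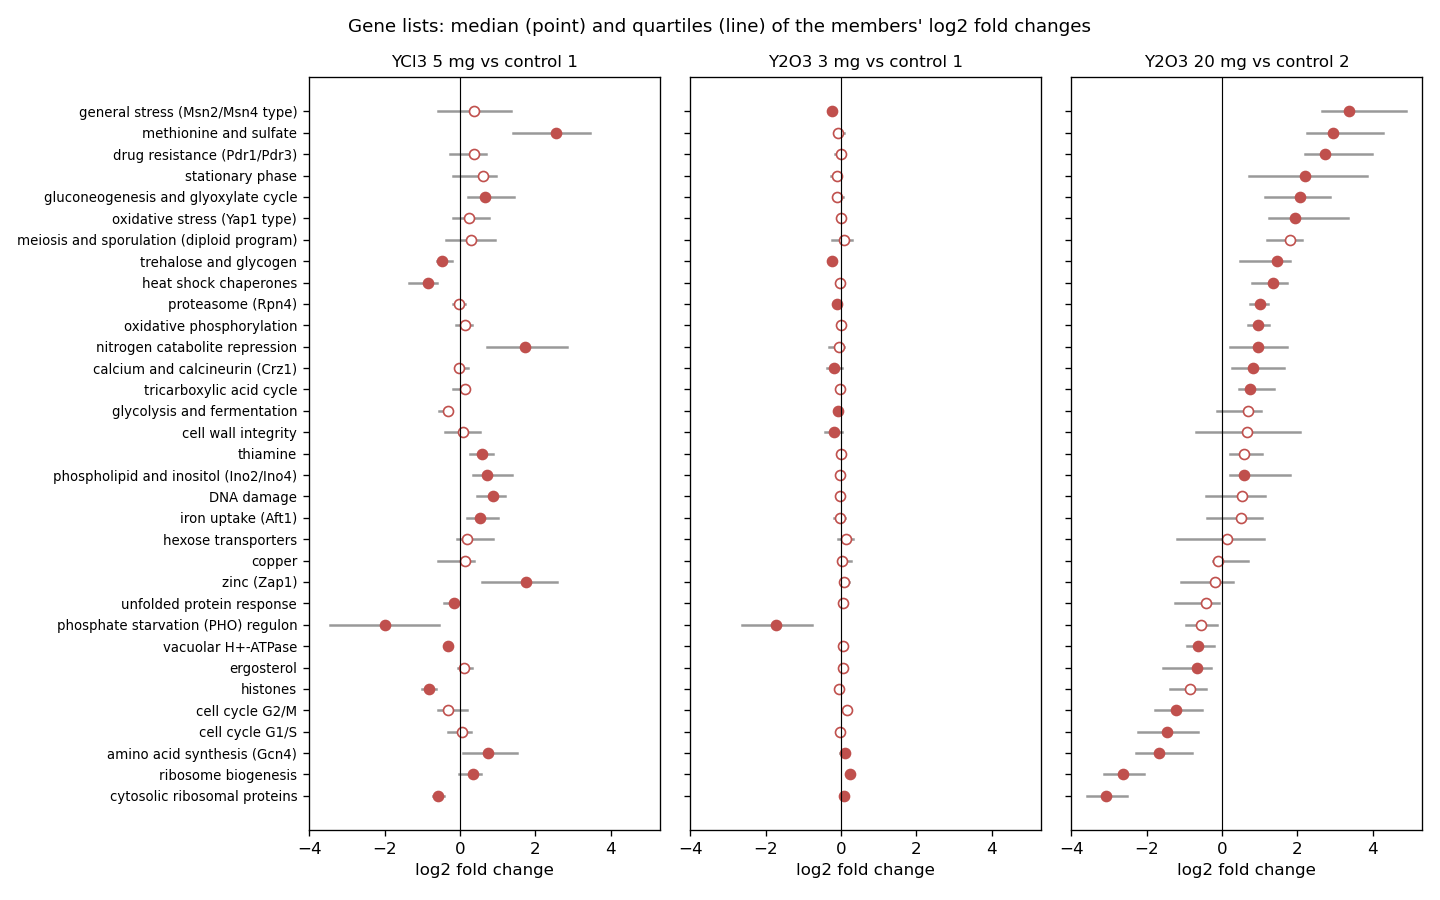
Median and quartiles of log2 change over the members of each list for the salt, 3 mg and 20 mg of oxide against their controls, with filled symbols for a camera adjusted p below 0.05 and open symbols for the others (n = 4 arrays per group). Ribosomal proteins had a median of -3.09 with 20 mg and 0.08 with 3 mg. No called list changed direction relative to the other genes under another scaling. The medians themselves moved, and that of G2/M with 20 mg was -0.03 with background modelled on the median signal.

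Compared directly, the salt and the 3 mg oxide differed in methionine and sulfate genes and in genes of nitrogen catabolite repression, whereas the phosphate list was not called. SUL1 was higher with the salt by 9.07 log2 units (standard error 0.47, n = 4, adjusted p = 1.46e-11, at least 158-fold), INO1 by 8.34 (0.66, adjusted p = 1.03e-08), MEP2 by 5.67 (0.15, adjusted p = 7.73e-16) and GAP1 by 5.35 (0.32, adjusted p = 1.75e-10). Lower with the salt were ARO10 (-8.63, 0.22, adjusted p = 5.78e-16), BAP3 (-6.90, 0.25, adjusted p = 8.49e-14), FRE7 (-6.50, 0.30, adjusted p = 2.6e-12), PTR2 (-6.48, 0.27, adjusted p = 5.95e-13) and ARO9 (-5.94, 0.25, adjusted p = 9e-13). PHO84 (-3.59, 0.46, adjusted p = 7.07e-06) and SPL2 (-2.14, 0.31, adjusted p = 3.15e-05) were also lower, while PHO5 did not differ detectably (-0.08, adjusted p = 0.889). The phosphate list had 5 of 19 members lower and 0 higher, with a median of -0.09 (adjusted p = 0.364). Limma called 1963 of 5717 genes, 931 higher and 1032 lower with the salt, 559 of them at least 2-fold, 379 higher and 180 lower. The arrays did not overlap for 2142 genes, or 37.5 percent, against 2.86 percent by chance. Form and amount both differed between these groups, so the comparison does not separate them.

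Of 34 lists, 17 differed between the salt and the 3 mg oxide, 12 higher and 5 lower with the salt, and 2 with an estimated correlation. Those 2 were methionine genes (median 2.89, 24 of 27 higher and 3 lower, adjusted p = 1.79e-19, and 0.0455 with an estimated correlation) and nitrogen catabolite genes (1.87, 19 of 24 higher and 1 lower, adjusted p = 3.85e-18, and 0.00106 with an estimated correlation). Zinc genes were higher by 1.58, with 10 of 13 higher and 2 lower (adjusted p = 1.95e-05, and 0.234 with an estimated correlation). Heat shock chaperones were lower by 0.93, with 18 of 23 lower and 2 higher (adjusted p = 5.31e-08, and 0.171 with an estimated correlation). Ribosomal proteins were lower by 0.64, with 70 of 136 lower, or 98 over the list alone (adjusted p = 1.54e-11, and 0.534 with an estimated correlation). With slide as a block 1973 genes and 18 lists were called, and within slides 1 and 2 alone 1033 and 239 genes and 20 and 13 lists. SUL1 differed by 9.03 and 9.11 within the 2 slides and ARO10 by -8.52 and -8.75, and the phosphate list by 0.12 and -0.33. Averaging the oxide arrays in pairs left 943 genes.

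The salt and the 3 mg oxide shared 14 genes that fell and 2 that rose, against 2.7 and 0.3 expected if the calls were independent. Both comparisons used the same controls, and fold changes across genes correlated at 0.154. With the controls split, replicates 1 and 3 for the salt and 2 and 4 for the oxide, 11 genes fell in both and the correlation was -0.165. In that split 9 genes changed in opposite directions. With the opposite split 9 fell in both, 0 changed in opposite directions and the correlation was 0.154. In 20 simulations with no effect the shared controls alone gave a mean correlation of 0.501, a covariance of 0.0247 and 0 genes called in both. The measured correlation and covariance were 0.154 and 0.0282. The simulated arrays held independent noise and no array like replicate 4 of control set 1, so they do not bound what the real controls could produce. The salt and the 20 mg oxide, which share no arrays, had 446 genes up in both and 494 down in both, against 314 and 408.9 expected. A further 534 genes changed in opposite directions, fewer than expected. Of these, 286 rose with the salt and fell with 20 mg, against 357.6 expected, and 248 did the reverse, against 359.1. The correlation of these 2 responses was 0.278. For 3 mg and 20 mg of oxide, 6 genes fell in both and 1 rose in both, against 5.1 and 0.7 expected, and the correlation was -0.429, or -0.048 without replicate 4 of control set 1.

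The response to 20 mg differed from that to 3 mg in 3646 of 5706 genes, 1730 higher and 1916 lower, each response being taken against its own controls. INO1 was higher by 11.74 log2 units (standard error 0.93, n = 4, adjusted p = 4.98e-09), PHO89 by 10.65 (1.02, adjusted p = 4.94e-08), RGI2 by 9.46 (0.61, adjusted p = 5.42e-10), OYE3 by 9.41 (0.41, adjusted p = 5.57e-12) and HXT5 by 8.53 (1.00, adjusted p = 5.9e-07). Lower with 20 mg were DBP2 (-6.57, 0.45, adjusted p = 1.04e-09), PHO3 (-6.41, 0.33, adjusted p = 5.61e-11), the weak acid pump PDR12 (-6.09, 0.58, adjusted p = 4.23e-08), MF(ALPHA)2 (-5.85, 0.42, adjusted p = 1.43e-09) and AAH1 (-5.46, 0.42, adjusted p = 3.31e-09). DBP2 and PHO3 were well above background on 0 arrays at 20 mg, so their differences are known only as bounds, of -5.32 each. The sizes for RGI2, MF(ALPHA)2 and AAH1 are uncertain for the reason given above, as is that for PDR12, well above background on 2 arrays at 20 mg. The phosphate list was higher by a median of 1.19, with 12 of 19 higher and 0 lower, or 13 over the list alone (camera adjusted p = 0.000915, and 0.299 with an estimated correlation). SPL2 was higher by 4.70 (0.44, adjusted p = 3.65e-08), PHO5 by 3.04 (0.57, adjusted p = 0.000128) and PHO84 by 2.04 (0.65, adjusted p = 0.00994). Without the 3 arrays in doubt these differences were 4.04 for SPL2, 1.72 for PHO5 (adjusted p = 5.93e-06) and 1.23 for PHO84 (adjusted p = 0.101). The mean of the phosphate list was -0.80 and -0.78 on replicates 1 and 2 at 20 mg and 0.05 and 0.24 on replicates 3 and 4, which are in doubt. In control set 2 it was -0.81 on replicate 1, also in doubt, and -0.41 to -0.37 on the other arrays. HSP12 was higher by 5.05 (0.66, adjusted p = 2.24e-06). Without replicate 4 of control set 1 the differences were 10.704 for INO1, 9.65 for PHO89, 7.45 for HXT5, -5.47 for PDR12 and 4.42 for HSP12.

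All 23 general stress genes tested were higher with 20 mg than with 3 mg, by a median of 3.78 (adjusted p = 6.11e-11, and 0.214 with an estimated correlation). All 65 ribosome biogenesis genes were lower, by 2.83 (adjusted p = 8.09e-20, and 0.214 with an estimated correlation). Ribosomal proteins were lower by 3.18, with 132 of 136 lower, or 133 over the list alone (adjusted p = 1.18e-31, and 0.214 with an estimated correlation). Proteasome genes were higher by 1.12, with 34 of 36 higher, or 35 over the list alone (adjusted p = 6.47e-10, and 0.178 with an estimated correlation). Of 33 lists 23 were called, and 0 with an estimated correlation. The lowest adjusted p was then 0.0883, while the fry test called 28. With background modelled on the median signal the median of all genes moved by 0.537, and the split became 2193 genes higher and 869 lower, or 71.6 percent higher against 47.4. The 2 oxide amounts were run on different slides with different controls, so amount and slide were separated only through those controls.

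The response to 20 mg differed from that to the salt in 3514 of 5725 genes, 1742 higher and 1772 lower. Form, amount and slide all differed here, and only slide was allowed for, through the controls. PHO89 was higher by 9.32 log2 units (standard error 1.02, n = 4, adjusted p = 2.94e-07), RGI2 by 8.82 (0.61, adjusted p = 1.37e-09), ARO10 by 7.86 (0.31, adjusted p = 2.25e-12), OSI1 by 7.73 (0.35, adjusted p = 1.02e-11) and the uncharacterised YCR102C by 7.0 (0.42, adjusted p = 4.89e-10). Lower with 20 mg than with the salt were DBP2 (-7.29, 0.45, adjusted p = 5.34e-10), ARG3 (-6.59, 0.40, adjusted p = 5e-10), AAH1 (-6.43, 0.42, adjusted p = 8.49e-10), ARG1 (-6.08, 0.40, adjusted p = 8.7e-10) and CSS1, a gene for a secreted protein (-5.70, 0.37, adjusted p = 8.49e-10). For DBP2, at background with 20 mg, the difference is known only as a bound, of -6.04, and the sizes for RGI2 and AAH1 are again uncertain. So is that for ARG3, well above background on 2 arrays at 20 mg. SPL2 was higher by 6.84 (0.44, adjusted p = 7.89e-10), PHO84 by 5.63 (0.65, adjusted p = 5.15e-07) and PHO5 by 3.12 (0.57, adjusted p = 0.000107), while ZRT1 was lower by 5.53 (0.30, adjusted p = 1.24e-10). Without replicate 4 of control set 1 the PHO89 difference was 8.32, and without the 3 arrays in doubt those of SPL2, PHO84 and PHO5 were 6.18, 4.82 and 1.8. The phosphate list was higher by a median of 1.60, with 13 of 19 higher and 0 lower by both adjustments (camera adjusted p = 0.000123, and 0.293 with an estimated correlation).

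All 24 general stress genes were higher with 20 mg than with the salt, by 3.37 (adjusted p = 2.48e-10, and 0.259 with an estimated correlation). Heat shock chaperones were higher by 2.38, with 22 of 23 higher and 1 lower (adjusted p = 1.89e-09, and 0.124 with an estimated correlation). Amino acid synthesis genes were lower by 2.41, with 42 of 48 lower and 0 higher (adjusted p = 1.89e-15, and 0.124 with an estimated correlation). Zinc genes were lower by 2.11, with 10 of 13 lower and 1 higher (adjusted p = 0.00104, and 0.3 with an estimated correlation), and nitrogen catabolite genes by 1.08, with 15 of 24 lower and 3 higher (adjusted p = 0.00302, and 0.204 with an estimated correlation). Methionine genes, which rose in both, were not called (median 0.34, adjusted p = 0.13). Of 34 lists 21 were called, and 0 with an estimated correlation. The lowest adjusted p was then 0.109, while the fry test called 26. The glycolysis list (adjusted p = 0.0223) was not called with quantile scaling (0.792), and background modelled on the median signal moved the median of all genes by 0.535. The split then became 2343 genes higher and 820 lower, or 74.1 percent higher against 49.6.

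Untreated cultures of the 2 experiments also differed. Rises from background in control set 1 were in YKL102C (4.66, standard error 0.66, n = 4, adjusted p = 2.84e-05, at least 11.1-fold), BSC4 (4.57, 0.64, adjusted p = 2.31e-05, at least 7.87-fold), YOL134C (4.37, 0.54, adjusted p = 7.51e-06, at least 4.89-fold) and YMR245W (4.36, 0.56, adjusted p = 9.78e-06, at least 6.32-fold), with YBR178W well above background on 1 array there (4.38, 0.55, adjusted p = 7.98e-06). PHO89 was lower in control set 2 by 3.23 log2 units (0.72, adjusted p = 0.00163, or -2.22 without replicate 4 of control set 1), the hexose transporter HXT2 by 2.35 (0.49, adjusted p = 0.000878) and SPO12, a regulator of mitotic exit, by 2.23 (0.17, adjusted p = 4.17e-08). CUP1-1 was higher by 1.40 (0.38, adjusted p = 0.00638), and ZRT1 and SPL2 were lower by 0.88 (0.21, adjusted p = 0.00259) and 0.96 (0.31, adjusted p = 0.0187). Limma called 2306 of 5637 genes, 1012 higher and 1294 lower, 562 of them at least 2-fold. With background modelled on the median signal the split became 625 higher and 459 lower, or 57.7 percent higher against 43.9. Proteasome genes were lower by a median of 0.63 with 22 members down (adjusted p = 6.19e-09, and 0.856 with an estimated correlation). Phosphate genes were lower by 0.49 with 7 down (adjusted p = 0.0181). Of 33 lists 9 were called, and 0 with an estimated correlation, while the fry test called 11. Slide, experiment and control set changed together here, so a difference between the control sets was a difference between experiments and not an effect of yttrium.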

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

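All tests of the 3 patterns weighed here were chosen after the results were seen, whereas the splits of the arrays into other groups were planned before the data were examined. The response to 20 mg of oxide differed from that to 3 mg in 3646 genes and 23 lists, and from that to the salt in 3514 genes and 21 lists. Genes higher with 20 mg than with 3 mg were INO1 (11.74), PHO89 (10.65), RGI2 (9.46), OYE3 (9.41), HXT5 (8.53), HSP12 (5.05), SPL2 (4.70), PHO5 (3.04) and PHO84 (2.04). Lower were DBP2 (-6.57), PHO3 (-6.41), PDR12 (-6.09), MF(ALPHA)2 (-5.85) and AAH1 (-5.46), where DBP2 and PHO3 lay at background with 20 mg and only a bound of -5.32 holds. Against the salt, PHO89 (9.32), RGI2 (8.82), ARO10 (7.86), OSI1 (7.73), YCR102C (7.0), SPL2 (6.84), PHO84 (5.63) and PHO5 (3.12) were higher, and DBP2 (-7.29), ARG3 (-6.59), AAH1 (-6.43), ARG1 (-6.08), CSS1 (-5.70) and ZRT1 (-5.53) were lower, with a bound of -6.04 for DBP2. The sizes named as uncertain above are uncertain here too.

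The first pattern is the change of 3983 genes with 20 mg, on arrays that were mostly dim. A linear effect of low array signal is argued against, since with array signal as a covariate 87.3 percent of the genes kept their call and direction. On slide 3 signal nearly went with treatment, and a linear term cannot remove an uneven effect near background. Set against the dim replicate 1 of control set 2 alone, replicates 1 to 3 at 20 mg gave changes with a median ratio of 0.981 to these. That control array had also entered the calls. Background modelled on the median signal moved the median change of all genes by 0.492, so an uneven effect on the sizes stays open. An effect of array row on every slide is argued against, since the arrays at 3 mg, in the same row, had slopes on these changes of at most -0.057. No flag or header used here names a fault of row 1 of slide 3, but by the layout its effect cannot be told apart from that of the oxide, since 0 arrays of the 20 mg group lay elsewhere.

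The second pattern is the fall of phosphate genes with the salt and with 3 mg of oxide. Spread between untreated cultures is argued against, since the lowest of the 8 control arrays lay 0.78 log2 units above the highest treated array in the list mean. Array row is argued against, since 10 of the 14 members that fell with 3 mg were higher with 20 mg relative to controls, although without the 3 arrays of slide 3 with the lowest percent of probes well above background this held for 5, GIT1, PHO5, PHO81, PHO89 and SPL2. There PHO84 (1.23, adjusted p = 0.101) and VTC3 (0.46, adjusted p = 0.208) lost their calls and 11 of the 14 fell with 20 mg as well, so for members outside those 5 the argument is weak. It is weak for GIT1 too, which was well above background on 1 array at 20 mg and 3 in control set 2. Leaving out those 3 arrays also removed the dim control array, replicate 1 of control set 2. Its phosphate list mean was -0.81, against -0.80 and -0.78 on the 20 mg arrays kept. Those dim arrays then faced brighter controls only, so signal and treatment cannot be told apart in that fit. Yttrium could bind phosphate and leave cells short of it, but such cells would raise these genes and 0 members rose. Culture stage, or less use of phosphate from the medium, was not tested and stays open.

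The third pattern is the opposite sign of changes with 3 mg and 20 mg, with a correlation of -0.429 across genes. Replicate 4 of control set 1 is a candidate explanation, since without it the correlation was -0.048, while without any other control of that set it was between -0.507 and -0.478. An opposite response to the smaller amount is argued against, since against the 3 other controls the slopes of the arrays at 3 mg were no lower than -0.019. What made that control array differ stays open.

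Splitting the same arrays into other groups of 4 argued against chance for the gene counts between 2 groups, if the arrays of a group were independent. If each oxide pair was 1 culture, too few groupings of whole cultures remain to exclude chance for the oxide comparisons. The real grouping was the only 1 of 35 to call as many genes for the salt (2077, highest other 397), for 3 mg (16, highest other 6), for 20 mg (3983, highest other 66), for the salt against 3 mg (1963, highest other 0) and for the control sets (2306, highest other 7). For the differences between responses it was the only 1 of 100 drawn splits, with 3646 against a highest other of 3597 for 3 mg and 3514 against 3365 for the salt. The high draws were the 3 and 4 that kept the 20 mg arrays apart from control set 2. They called 3317 to 3597 and 3136 to 3365 genes, and the other draws reached at most 13 and 210. Most of each count thus came with the 20 mg grouping alone, so the draws do not exclude chance for a difference between responses. For the list counts chance was not excluded, because splits with as many lists or more, the real one included, numbered 5 of 35 for the salt (18, highest other 23), 30 for 3 mg (10, highest other 19), 13 for 20 mg (21, highest other 24) and 8 for the salt against 3 mg (17, highest other 20). Of 100 draws they numbered 13 for 20 mg against 3 mg (23, highest other 24) and 22 for 20 mg against the salt (21, highest other 27).

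Of 302 groups of 4 values examined, 28 had 1 array set apart by a gap over Dixon's critical value for 4 samples, a rule that chance meets in about 5 percent of groups. Replicate 4 of control set 1 was set apart for GAP1 (gap over range 0.897), PHO84 (0.888), KAR2 (0.887), PMC1 (0.885), PUT4 (0.878), PHO11 (0.849), the phosphate list mean (0.839), INO1 (0.831) and PHO89 (0.831). With the salt, replicate 3 was high for HSP26 (0.909) and replicate 4 for RPL41A (0.901). In control set 2, replicate 1 was set apart for MF(ALPHA)2 (0.913), the phosphate list mean (0.909), GRE1 (0.894), MCD1 (0.888), the percent of probes well above background (0.855), GND2 (0.843) and RPL24A (0.835), and replicate 2 for PIR3 (0.972), NOP1 (0.965) and ECM4 (0.868). With 20 mg, replicate 4 was set apart for array signal (0.949), ITR1 (0.917), ZRT1 (0.881), RPL24A (0.872), CLB6 (0.859), PIR3 (0.857) and PDR10 (0.844).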

How the results depend on the processing

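Most other choices of processing were set before the data were examined, and the background model on the median signal, array signal as a covariate, the arrays in doubt left out and the oxide arrays in pairs were chosen after. Of 345 alternative values of the counts and correlations, 315 stayed within the bounds set. Of 5721 alternative values of named genes, 5611 stayed called or uncalled as before, 50 of these with a turned sign but not called in either setting. A call was lost in 80 and gained in 28, and 2 turned direction. Those 2 came with background modelled on the median signal at 20 mg, where CLB6 changed by 0.588 and ZRT1 by 1.049. This tally of named genes sets no bound on size. RNR3 with the salt, for example, moved from 3.37 to 4.36 without salt replicate 4 and stayed called. Except where fewer arrays, fewer genes or a stricter test explain a lower count by construction, the cause was not tested.

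A minimum of 2-fold left 561 genes for the salt, 2204 for 20 mg, 559 for the salt against 3 mg, 2427 and 2295 for the response to 20 mg against those to 3 mg and to the salt, and 562 between the control sets. An estimated correlation left 1 list for the salt, 1 for 3 mg, 0 for 20 mg, 2 for the salt against 3 mg and 0 for both differences between responses, and fry called 1 list for 3 mg. Fitting only the groups of the comparison gave 1205 genes for the salt. For 20 mg, no filter on dim probes gave 4562 genes and only probes well above background on all arrays 3481.

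Within slides 1 and 2 alone there were 1026 and 308 genes for the salt, 9 and 3 for 3 mg, and 1033 and 239 for the salt against 3 mg. With background modelled on the median signal there were 907 genes for the salt, 937 for the salt against 3 mg and 1084 between the control sets. The salt and 20 mg then shared 439 genes in direction, and the correlation of 3 mg with 20 mg was -0.37. Averaging the oxide arrays in pairs gave 943 genes for the salt against 3 mg. With replicates 1 and 3 of the controls used for the salt, its correlation with 3 mg turned to -0.165, and with replicates 2 and 4 the shared genes numbered 10.

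Leaving out each array in turn gave 1578 to 2299 genes for the salt, 14 to 17 for 3 mg, 3816 to 3944 for 20 mg and 1533 to 2239 for the salt against 3 mg. Lists for 3 mg ranged from 1, without replicate 4 of control set 1, to 13, without replicate 3. Without replicate 4 the correlation of 3 mg with 20 mg was -0.048, against -0.507 at the other end. With replicate number as a block there were 2037, 17 and 3992 genes for the salt, 3 mg and 20 mg.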

Other observations

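The groups in this part were chosen after their values were seen, and were taken from families of genes with a shared name and at least 8 members, or from the 20 amino acid permeases. Seripauperin genes (PAU), a family of similar cell wall proteins, rose with 20 mg of oxide in 24 of 24 members, by a median of 1.73 (camera adjusted p = 1.78e-07, and 0.565 with an estimated correlation), and with the salt in 9 of 24, by 0.51 (adjusted p = 0.00229, and 0.737 with an estimated correlation). Autophagy genes (ATG) rose with 20 mg in 26 of 32 members with 0 down, by 1.38 (adjusted p = 1.78e-07, and 0.464 with an estimated correlation). Adenine synthesis genes (ADE) fell in 10 of 11, by 1.87 (adjusted p = 0.00176), and translation initiation genes (TIF) in 10 of 10, by 1.49 (adjusted p = 0.00176), each at 0.464 with an estimated correlation. Genes of the large mitochondrial ribosomal subunit (MRPL) fell with the salt in 15 of 34 members, by 0.41 (adjusted p = 0.000235, and 0.677 with an estimated correlation). With 20 mg their median was -0.62, and 0.05 with background modelled on the median signal.

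Amino acid permeases changed in both directions with the salt, with 9 of 20 up and 9 down by limma. Among the falls were BAP3 (-6.76), DIP5 (-4.97), TAT1 (-4.88), BAP2 (-4.59) and GNP1 (-4.23). Among the rises were GAP1 (4.95), PUT4 (4.74), and MMP1 (2.53) and SAM3 (2.07), which carry S-methylmethionine and S-adenosylmethionine. With background modelled on the median signal AGP2 (-0.67), SSY1 (0.44) and AGP3 (1.11) were not called with the salt. With 3 mg of oxide limma called 0 of these permeases, and 164 of all genes had an unadjusted p below 0.05, fewer than chance alone would give. With 20 mg, 9 of 19 rose and 8 fell, among them the methionine permeases MUP3 (3.34) and MUP1 (2.77), which rose, and TAT1 (-3.58). MUP1 fell with the salt (-2.12), against the direction of most methionine genes. DIP5 fell with 20 mg (-1.03) but was not called with background modelled on the median signal (0.20).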
